A study of Mus musculus with 11 samples.

How the data were processed

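The series holds 11 arrays of total RNA from C57B6 mice of both sexes aged 2 months, per the labels. There are 3 arrays of carotid body, 4 of adrenal medulla and 4 of superior cervical ganglion. Each carotid body replicate was a pool from 10 mice and each adrenal medulla or ganglion replicate a pool from 3 mice, per the series' design text, so a replicate here is a pool and not an animal. RNA was isolated with a column kit, amplified with the WT PLUS reagent kit and hybridised to an Affymetrix mouse transcriptome 1.0 array, per the labels' protocols. The labels do not say how the mice were divided among the pools, and they give no scan date or batch.

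The deposited values are log2 signals that the authors made with RMA (robust multi-array average, which corrects background, normalises arrays to a common distribution and summarises the probes of each transcript cluster) in Affymetrix Expression Console, per the submitters' processing notes. No version of either is given in the sources used here. The log base is taken as 2 because RMA uses it. The highest value of each array lay between 19.65 and 19.93, and 182 to 276 genes per array lay above 16, the log2 limit of a 16-bit scan, so a rescaling step that no source names is possible. Every difference and fold below is therefore on the scale of the deposited values. The medians of the tested genes were 5.64, 5.63, 5.64 and 5.64 on adrenal medulla replicates 1 to 4, then 5.70, 5.84 and 5.82 on carotid body replicates 1 to 3, and 5.82, 5.73, 5.67 and 5.68 on ganglion replicates 1 to 4. The direction and centring of the values follow from RMA. Raw scans were not analysed here.

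The value table has 72688 features, of which 6732 are controls and 65956 are transcript clusters. Names came from the array's annotation, in which 30607 clusters pair with 1 gene symbol, 2143 with several and 33206 with none. Clusters with several symbols or none were left unnamed and out of the tests. Where a gene had several clusters (355 genes), the brightest by its mean over all arrays was used, which left 30145 genes. Symbols were updated for 819 genes through Entrez identifiers in a RefSeq gene table of the GRCm38.p6 assembly, which held 22403 of the genes and marked 18817 as protein-coding. That table was used for names and gene types only, and no coordinates are given because the array's build is not stated. Of the genes tested, 452 share all 11 values with another gene (128 such profiles, the largest with 48 genes), and 13 of these genes are protein-coding.

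Tissue was the only factor in a single limma fit over the 11 arrays (lmFit and eBayes, limma 3.58.1 in R 4.3.3), from which 3 contrasts were taken: carotid body minus adrenal medulla, carotid body minus ganglion and adrenal medulla minus ganglion. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, a 2-fold difference. Every adjusted p of a gene is from limma's moderated test. Genes called higher in a tissue than in both others, and genes called in the same direction against the ganglion in both other tissues, were counted from the same calls. No dim gene was removed before the main fit. A background bound was set in each tissue at the 95th percentile of the tissue means of 347 genes of the vomeronasal receptor and keratin-associated protein families, taken as silent here: 5.35 in adrenal medulla, 5.38 in carotid body and 5.45 in ganglion. Where a tissue's mean lay under its bound, the fold was computed against the bound and is given as "at least". Where the mean lay above the bound but single arrays under it, those arrays were set to the bound and the fold is given in the same way, a step added after the values were seen. The same words are used where the brighter tissue's mean lay within 0.5 of the array's maximum, and no fold is given where both tissues were under the bound or both near the maximum.

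A total of 41 gene lists (functional families, markers of cell types, technical reference sets) were written before the data were examined, as were the test, its thresholds, the naming rule and most of the alternatives. The 38 lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 114 list tests, and again with the correlation estimated from the residuals. Ranges of a list's adjusted p over the alternatives leave out the estimated correlation, whose value is given apart. Members called were counted with the adjustment over all genes and with the adjustment over the list alone. Genes are named in the text by a fixed rule: in each contrast and direction, the 10 called genes with the largest difference whose tissues do not overlap; for each tissue, the 10 with the largest smaller difference over both others; up to 4 called members of each list and contrast with the largest difference; and a set of genes of long-standing interest in carotid body work. Predicted genes, clones, small RNAs and immunoglobulin or T-cell receptor segments were left out of that rule. Genes named outside it are said to be.

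The fit was tested on simulated data made from the mean over all arrays and the fitted spread of each of the 30145 genes. The spread was the same in every tissue, and 100 genes were changed by 1.5 log2 units and 100 by 3. For carotid body against adrenal medulla 98 and 99 of these were recovered, for carotid body against ganglion 95 and 100, and for adrenal medulla against ganglion 99 and 100, while 2, 1 and 0 unchanged genes were called. Some real genes, such as Dbh and Nefl, spread more among carotid body arrays than among those of either other tissue. The recoveries therefore do not test the fit under unequal spread. Camera found a simulated list of 20 genes moved by 1 in both contrasts that held it, and no shift in 60 tests of unmoved lists. The simulated genes varied independently of each other. The camera simulation therefore does not give the rate of false shifts in real lists, where the estimated correlation reached 0.65 (neuron structure and synapse) and 0.74 (skeletal muscle). Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

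The alternatives were an intensity trend with a robust prior, array weights, median centring, repeated quantile normalization, a filter on dim genes, the mean of a gene's clusters, all features tested, no fold limit, the arrays of the compared tissues alone, the replicate number as a block, each array left out in turn, camera with an estimated correlation and camera on ranks. A covariate for the gap between the positive and negative control features, identical profiles counted once, protein-coding genes only and list counts without each array were chosen after seeing the data. Counts that rest on contrasts with shared arrays were set beside simulated unchanged groups (20 simulations), the product of independent lists and, where a tissue has 4 arrays, 6 ways to split its arrays. The small number of arrays per tissue limits the precision of every value.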

Results

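The series profiled RNA from a trio of mouse organs that derive from the neural crest and make catecholamines. The carotid body is the arterial chemoreceptor that senses blood oxygen, the adrenal medulla is the hormone-secreting core of the adrenal gland, and the superior cervical ganglion holds sympathetic neurons. Expression was measured in pooled tissue on 3 carotid body arrays, 4 adrenal medulla arrays and 4 ganglion arrays, and 30145 named genes were compared. Values are log2 expression values, given as the mean ± SD over n = 3 arrays of carotid body or n = 4 of either other tissue, and differences carry their standard error (SE) where it is given. Between 54.3% and 56.6% of the genes had a tissue mean above the background bound (16356 genes in adrenal medulla, 17050 in carotid body, 16357 in ganglion). Across genes, which are not independent replicates, Pearson's r between arrays of one tissue was 0.9944 to 0.9962 in adrenal medulla, 0.9854 to 0.9923 in carotid body and 0.9895 to 0.9956 in ganglion. Between tissues it was 0.9363 to 0.9495 for carotid body with adrenal medulla, 0.9212 to 0.9638 for carotid body with ganglion and 0.9085 to 0.9223 for adrenal medulla with ganglion.

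The comparison of carotid body with adrenal medulla asks what sets the oxygen-sensing organ apart from the adrenal samples. Epas1, which encodes the hypoxia-inducible factor HIF-2alpha, averaged 16.74 ± 0.48 in carotid body (transcript cluster TC1700001299.mm.1) and 12.73 ± 0.05 in adrenal medulla, a 16.1-fold difference (log2 4.01, SE 0.28, limma adjusted p = 1.66e-06). Rgs5, a regulator of G-protein signalling also abundant in pericytes, averaged 19.04 ± 0.20 against 13.57 ± 0.09 and was 44.3-fold higher. Chga, which encodes the granule protein chromogranin A, was lower in carotid body by 4.88 (at least 29.4-fold), at 14.84 ± 0.51 against 19.72 ± 0.02, close to the highest value of the adrenal medulla arrays. Pnmt, the enzyme that turns noradrenaline into adrenaline, averaged 5.57 ± 0.11 in carotid body and 14.13 ± 0.68 in adrenal medulla, a 378-fold difference.

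In all, 3320 genes were called between carotid body and adrenal medulla, 1828 higher and 1492 lower in carotid body (5157 and 3236 higher with all features tested). Median centring of the arrays turned this split to 1577 higher and 1966 lower (44.5% higher against 55.1%), as it moved the median difference of all genes from 0.05 to -0.10, so the balance of directions is not fixed by these data. Identical profiles counted once left 1627 higher and 1490 lower. Among protein-coding genes 1001 were higher and 1210 lower. A difference of at least 8-fold was found for 333 genes higher and 141 lower. The named genes with the largest differences towards carotid body were Car3 (carbonic anhydrase 3, 14.55 ± 0.65 against 4.87 ± 0.13, at least 589-fold), Cyp2e1 (a cytochrome P450, at least 279-fold), Dgkh (a diacylglycerol kinase, 196-fold), Acta2 (smooth muscle actin, 165-fold), Cdo1 (cysteine dioxygenase, 162-fold), Kcna1 (a voltage-gated potassium channel, 138-fold), Cpa3 (a mast cell protease, at least 110-fold), Akap12 (a kinase anchor, 105-fold), Ccl11 (a chemokine, 103-fold) and Cytl1 (a secreted cytokine-like protein, at least 77.2-fold). Towards adrenal medulla they were the steroidogenic genes Cyp11b1, Cyp11a1, Star, Hsd3b1 and Cyp21a1, followed by Abcb1b (a drug transporter, 952-fold), Akr1cl (an aldo-keto reductase, at least 412-fold), Pnmt, Slc18a1 (229-fold) and Lgr5 (a receptor of the Wnt pathway, 136-fold).

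Of 15 genes for catecholamine synthesis and transport, 8 were lower and 1 was higher in carotid body than in adrenal medulla. The same counts held adjusted over the list alone, while 3 were higher without carotid body replicate 2, and with a covariate for the control features 3 were higher and 4 lower. Th, the rate-limiting enzyme of catecholamine synthesis, averaged 17.69 ± 0.65 in carotid body and 19.57 ± 0.09 in adrenal medulla (at least 3.66-fold lower, limma adjusted p = 0.000106). Dbh, which makes noradrenaline, averaged 17.68 ± 1.47 in carotid body and 19.84 in adrenal medulla, where all 4 arrays sat at the top of their range (at least 4.47-fold lower in carotid body, at least 7.32-fold without carotid body replicate 1 and at least 2.65-fold without replicate 2), and was no longer called with that covariate. Ddc, which makes dopamine, differed by 0.83, under the 2-fold limit (called without carotid body replicate 2, at 1.07, and with the covariate, at 1.70). Gch1, which supplies the cofactor of tyrosine hydroxylase, was 5.48-fold lower in carotid body, and Slc18a1, a vesicular monoamine transporter, was lower by 7.84. Slc18a2, the other vesicular monoamine transporter, averaged 13.30 ± 0.74 against 13.56 ± 0.22 and was not called. Slc6a2, the noradrenaline transporter, was the member that was higher in carotid body (14.94 ± 1.83 against 11.58 ± 0.47; 2.40 without carotid body replicate 1 and 4.23 without replicate 2). The list as a whole was shifted towards adrenal medulla (median difference -1.41, camera adjusted p = 0.0012, but adjusted p = 0.439 with an estimated correlation).

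**Figure D1:**
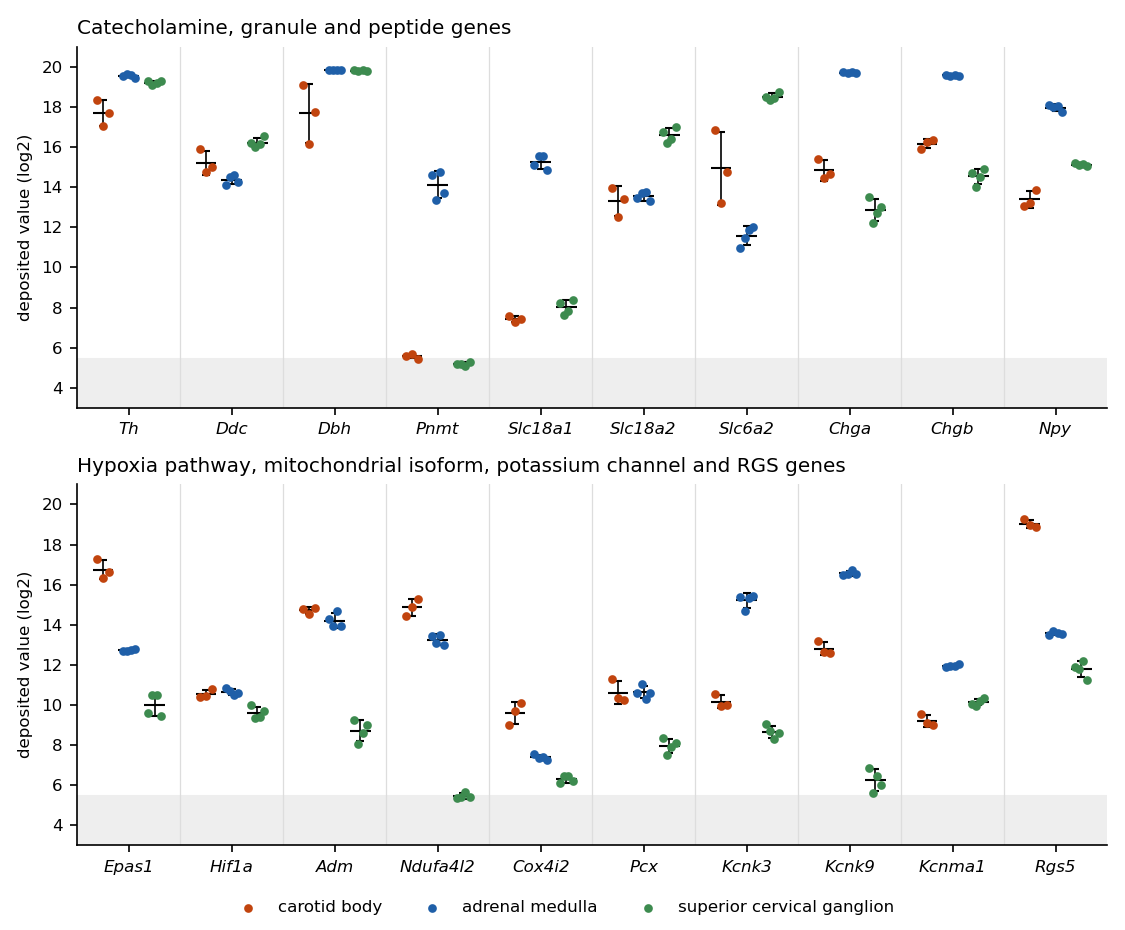
Deposited log2 value (vertical axis) of 20 named genes on each array of the 3 tissues, with bars for the mean ± SD and a grey band below the highest background bound. Epas1 and Rgs5 are highest in carotid body, Pnmt and Kcnk3 in adrenal medulla and Slc6a2 in ganglion, and Slc6a2 and Dbh spread most among the carotid body arrays.

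Of 14 dense core granule genes, 7 were lower in carotid body than in adrenal medulla and none was higher, and the same counts held adjusted over the list alone (4 were lower with the covariate). Chgb (chromogranin B) was at least 10.6-fold lower, Scg2 (secretogranin II) 21.5-fold lower and Pcsk1, a prohormone convertase, 73.7-fold lower. This list was shifted with a median difference of -1.23 (camera adjusted p = 1.09e-06, adjusted p = 0.323 with an estimated correlation). Among 19 neuropeptide genes, Npy fell below the adrenal medulla level by 4.58 (13.40 ± 0.43 in carotid body) and Gal (galanin) was lower by 4.27, while Vip was 3.15-fold higher in carotid body. Of 15 sympathoadrenal transcription factors, 1 was higher and 7 were lower, among them Tfap2b (20.8-fold), Hand1 (6.37-fold) and Gata2 (5.72-fold), which guide the development of this cell lineage. That shift (camera adjusted p = 0.0153, adjusted p = 0.497 with an estimated correlation) was lost under median centring (0.0602), with the covariate (0.254), with protein-coding genes only (0.0736) and without dim genes (0.0995), in a range of 0.000214 to 0.254.

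Among 18 genes of the hypoxia-inducible factor pathway, Epas1 and Ndrg1, a stress-response gene induced by hypoxia, were higher in carotid body than in adrenal medulla (5.56-fold for Ndrg1). Arnt2, a partner subunit of the factors, was 4.51-fold lower. Hif1a was not called (10.54 ± 0.22 against 10.66 ± 0.15, adjusted p = 0.637), nor was the vasodilator peptide gene Adm (adjusted p = 0.197). Of 10 genes listed as tissue-restricted mitochondrial isoforms, Cox4i2, a cytochrome oxidase subunit, was 4.66-fold higher in carotid body at 9.61 ± 0.56, and Ndufa4l2, a hypoxia-induced paralogue of Ndufa4, was 3.09-fold higher at 14.88 ± 0.43. Cox8b, another oxidase subunit, and Pcx (pyruvate carboxylase, an enzyme on this list but not an isoform) were not called, at differences of 0.46 and -0.02. Ndufa4 was called at 1.10 (adjusted p = 0.0165) but not without carotid body replicate 2 (1.03) or replicate 3 (0.87), nor under median centring (0.95), and with the covariate its difference turned to -0.0758. Complex I showed 1 lower gene of 33, Ndufs8, by 1.82 (2 lower with the covariate). The list of pyruvate and citric acid cycle genes was shifted lower in carotid body (7 of 29 lower, 2 higher, camera adjusted p = 0.00176, adjusted p = 0.426 with an estimated correlation). With the covariate 4 were lower and the shift was lost (0.176, in a range of 2.44e-06 to 0.176). Me1 (malic enzyme) was lower by 4.76 and Got1 by 3.27, while Pdk4 and Pck1, a kinase and a carboxykinase, were 26.6-fold and at least 23.9-fold higher.

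Potassium channels divided between the tissues. Kcnk3 and Kcnk9, which encode the acid- and oxygen-sensitive TASK channels, were 33.1-fold and 13.6-fold lower in carotid body than in adrenal medulla, at 10.16 ± 0.32 and 12.81 ± 0.34. Kcnk2 was 12.8-fold lower and Kcnma1, the large-conductance calcium-activated channel, 6.71-fold lower, while Kcnmb1, a partner subunit of it, was 4.38-fold higher. In all 5 of these 19 tandem-pore and large-conductance genes were lower and 1 was higher (2 higher without adrenal medulla replicate 2 or 4 or with the replicate number as a block, and 3 higher and 4 lower with the covariate), so the list was not shifted as a whole (camera adjusted p = 0.665, median 0.04, mean -0.56). Of 33 voltage-gated potassium channel genes 6 were higher and 1 lower (8 and 0 without carotid body replicate 2, 10 and 0 with the covariate), led by Kcna1 (14.25 ± 0.46 against 7.14 ± 0.41) and Kcna2 (20.8-fold). Scn7a, a sodium channel found in glia and sensory neurons, was 43.3-fold higher. Cacna1d and Cacna2d1, subunits of voltage-gated calcium channels, were 8.35-fold and 5.06-fold lower. Cacna1h, the T-type channel, was lower by 1.11 and fell by 0.97, under the limit, without adrenal medulla replicate 4. The adrenal medulla arrays also carried adrenal cortex genes near the top of the range. Which cells of those samples held the channel transcripts was not tested, here or in the comparison with ganglion.

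Among 21 RGS genes, 5 were higher and 2 lower in carotid body than in adrenal medulla (1 lower without adrenal medulla replicate 1 or 3, 3 higher under median centring, and 2 higher and 2 lower with the covariate), with Rgs4 7.45-fold higher and Rgs2 7.21-fold lower. Of 16 carbonic anhydrases 1 was lower and 4 were higher, namely Car3, Car5b (15.2-fold), Car2 (10.8-fold) and Car12 (at least 5.85-fold), and that list was shifted (camera adjusted p = 0.0137, adjusted p = 0.342 with an estimated correlation), though not on ranks (0.0562, in a range of 0.00764 to 0.0562). Htr3a and Htr3b, the subunits of the serotonin-gated channel, were 56.6-fold and 28.3-fold higher. These folds were 31.8 and 17.6 without carotid body replicate 1 and 103 and 48.4 without replicate 2. P2ry12, a nucleotide receptor, was 4.41-fold higher. Hmox1, the inducible haem oxygenase, was 32.4-fold lower in carotid body, Hmox2 was not called (9.10 ± 0.06 against 9.06 ± 0.15), whereas Prkaa1, a catalytic subunit of AMP-activated kinase, differed by -0.95, under the limit (called without carotid body replicate 1, at -1.20, and at -1.10 with array weights or median centring).

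Marker lists of other cell types set the background for all of these differences, since whole tissues were hybridised. All 14 fibroblast and matrix genes were higher in carotid body than in adrenal medulla, such as Mfap5 (79.3-fold), Fn1 (59.2-fold) and Col1a1 (14.18 ± 0.22 against 8.57 ± 0.11). The shift held with an estimated correlation (median difference 4.66, camera adjusted p = 1.04e-18, adjusted p = 0.00676 with an estimated correlation). Of 13 glial genes 8 were higher, led by Cdh19 (35.1-fold), Fabp7 (11.5-fold) and Erbb3 (7.80-fold). This shift held as well (camera adjusted p = 4.85e-08, adjusted p = 0.0378 with an estimated correlation). Of 13 adrenal cortex genes 12 were lower (camera adjusted p = 1.04e-18, adjusted p = 0.0347 with an estimated correlation). Cyp11b1, an enzyme of corticosterone synthesis, averaged 19.61 ± 0.13 in adrenal medulla against 4.99 ± 0.11, under the background bound, in carotid body. Of 12 adipocyte genes 9 were higher, among them Retn (at least 39.1-fold), Fabp4 (23.1-fold) and Adipoq (at least 15.9-fold). Their camera adjusted p was 2.78e-09, and adjusted p = 0.125 with an estimated correlation. Of 15 pericyte and smooth muscle genes 9 were higher, including Acta2, Myh11 (57.1-fold) and Tagln (14.8-fold), with camera adjusted p = 7.35e-08 and adjusted p = 0.126 with an estimated correlation. Endothelial genes went both ways, with 4 of 15 higher (Vwf 5.26-fold, Cdh5 2.41-fold) and 4 lower (Plvap 9.23-fold, Emcn 4.69-fold, Kdr 3.75-fold). Of 24 genes of neuron structure and synapse 10 were higher and 1 lower (16 and 1 with the covariate), with Tubb3, Prph, Ret and Gap43 higher by 5.33, 4.96, 4.17 and 4.12 (camera adjusted p = 0.000968, adjusted p = 0.647 with an estimated correlation). For Tubb3, Prph and Ret the differences were 4.68, 4.24 and 3.39 without carotid body replicate 1 and 6.04, 5.67 and 5.02 without replicate 2. Of the 1828 genes higher in carotid body, 809 were also called higher in ganglion than in adrenal medulla. Both comparisons share the adrenal medulla arrays: unchanged simulated groups gave 0 such genes, independent lists would overlap in 137, and splits of the adrenal medulla arrays gave 726 to 908. No gene of the simulated groups was changed, so their 0 does not show what the shared arrays add among changed genes.

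**Figure D2:**
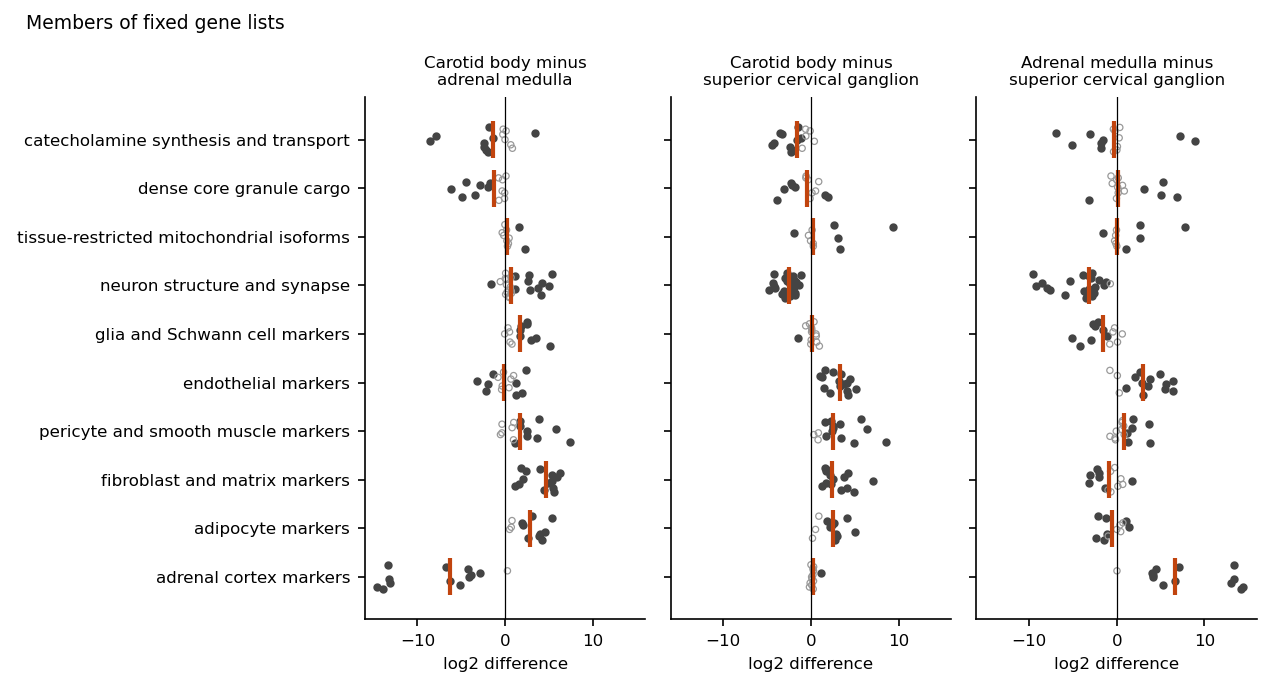
Log2 difference (horizontal axis) of each member of 10 fixed gene lists in the 3 comparisons, with filled points for called genes, open points for the others and a red bar at the list's median. The fibroblast list lies to the right of 0 in both carotid body comparisons, the adrenal cortex list lies far from 0 only where the adrenal medulla is compared, and all 24 neuron genes lie left of 0 for carotid body against ganglion.

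The comparison of carotid body with superior cervical ganglion sets the chemoreceptor organ against a sympathetic ganglion. Ndufa4l2 averaged 14.88 ± 0.43 in carotid body and 5.46 ± 0.14 in ganglion, where 3 of 4 arrays lay under the background bound, a difference of at least 665-fold (fitted log2 9.42, SE 0.19, limma adjusted p = 7.74e-10). Epas1 was 107-fold higher in carotid body (10.00 ± 0.54 in ganglion), Kcnk9 95.2-fold higher (6.23 ± 0.55 in ganglion) and Rgs5 153-fold higher (11.79 ± 0.39 in ganglion). Htr3a went the other way, at 13.16 ± 1.69 in carotid body and 18.30 ± 0.14 in ganglion, as did the neurofilament gene Nefl, lower in carotid body by 4.79 (Htr3a by 5.97 and 4.28, and Nefl by 5.67 and 3.89, without carotid body replicates 1 and 2).

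Here 4187 genes were called, 1691 higher and 2496 lower in carotid body (2791 and 1011 higher with the covariate, and 2885 higher with all features tested). Repeated quantile normalization gave 2150 higher and 2049 lower (51.2% higher against 40.4%), so the balance of directions depends on the scaling. A difference of at least 8-fold was found for 168 genes higher and 321 lower, and protein-coding genes accounted for 1014 of those higher and 1963 of those lower. After Ndufa4l2, the largest differences towards carotid body were those of Gdf10 (a growth factor, at least 603-fold), Acta2 (386-fold), Mgp (matrix Gla protein, 280-fold), Rgs5, Igfbp3 (a binding protein of insulin-like growth factors, 148-fold), Dpt (dermatopontin, 136-fold), Epas1, Itga8 (an integrin, 96.6-fold) and Kcnk9. Towards ganglion they included Cxcr4 (a chemokine receptor, 40.9-fold), Napb (a protein of vesicle fusion, 36.7-fold), Htr3a (35.4-fold), Nrip3 (29.5-fold), Htr3b (29.0-fold), Sult4a1 (a neuronal sulfotransferase, 27.8-fold) and Nefl (27.7-fold). Without carotid body replicate 1 the folds were 470 for Mgp, 69.8 for Napb, 62.9 for Htr3a, 50.8 for Nefl, 46.7 for Htr3b and 41.9 for Sult4a1. Without replicate 2 they were 20.9 for Napb, 19.5 for Htr3a, 16.9 for Htr3b and 14.8 for Nefl.

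Of 15 catecholamine genes 10 were lower in carotid body than in ganglion and none was higher, with the same counts adjusted over the list alone (median difference -1.56, camera adjusted p = 1.52e-05, adjusted p = 0.338 with an estimated correlation). With the covariate 6 were lower. Th was 2.87-fold lower (19.22 ± 0.10 in ganglion; no longer called with the covariate, at -0.83), Slc18a2 9.81-fold lower and Maob, a monoamine-degrading enzyme, 18.4-fold lower. Ddc was just under the limit and was called without carotid body replicate 1 (-1.33) and without ganglion replicate 1 (-1.01), 2 (-1.08) or 3 (-1.02), as well as with array weights (-1.08) and median centring (-1.06). Chga and Chgb were higher in carotid body, by 1.98 and 1.64, while Pcsk1 was 8.31-fold lower and Npy 3.34-fold lower, and the granule list as a whole was not shifted (2 of 14 higher, 5 lower, 3 and 3 with the covariate, camera adjusted p = 0.301). Transcription factors of the sympathoadrenal lineage were lower for 7 of 15, with Tfap2b lower by 3.91 and Hand1 by 3.04 (camera adjusted p = 0.0172, adjusted p = 0.505 with an estimated correlation). That shift was lost on ranks (0.0562), with the covariate (0.0563, and 4 lower) and with protein-coding genes only (0.0612), in a range of 0.000727 to 0.0612.

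In the hypoxia-inducible factor pathway, Epas1, Adm (63.9-fold), Vegfa (an angiogenic growth factor, 4.29-fold; not called with the covariate, at 1.26) and Arnt2 (3.42-fold) were higher in carotid body than in ganglion and Egln3, a prolyl hydroxylase of the factors, 4.24-fold lower. The list of 18 was not shifted (camera adjusted p = 0.0816, adjusted p = 0.364 with an estimated correlation), except under repeated quantile normalization (0.0432), with a covariate for the control features (0.0197) and without carotid body replicate 2 (0.0453). Over the alternatives other than the estimated correlation the range was 0.0197 to 0.225. Hif1a differed by 0.95, under the limit, and was called without carotid body replicate 1 (1.02), carotid body replicate 2 (1.00) or ganglion replicate 1 (1.07), with array weights (1.13), with the covariate (1.29) and under repeated quantile normalization (1.22). Of 10 genes on the mitochondrial isoform list 4 were higher (Ndufa4l2, Cox4i2 at 9.86-fold, Cox8b at least 6.61-fold and the enzyme gene Pcx at 6.29-fold) and Higd1a, a hypoxia-inducible mitochondrial protein, was 3.67-fold lower (camera adjusted p = 0.0114, adjusted p = 0.195 with an estimated correlation). On ranks this shift was lost (0.0528, in a range of 0.00334 to 0.0528). The 4 higher genes also belong to the set of long-standing interest, so this list may reflect earlier carotid body work. The genes called in the core respiratory chain and glycolysis were lower in carotid body, though most respiratory chain genes were not called. Of 38 genes of complexes II to V 11 were lower, with Sdhd and Cycs lower by 2.01 and 1.70 (camera adjusted p = 3.03e-07, adjusted p = 0.364 with an estimated correlation; 5 lower under repeated quantile normalization). Of 18 glycolysis genes 11 were lower, with Slc2a3, a glucose transporter, and Aldoc, an aldolase, lower by 3.72 and 3.48 (camera adjusted p = 2.55e-05, adjusted p = 0.379 with an estimated correlation). Complex I was shifted lower with 4 of 33 genes called (8 with the covariate and 2 under repeated quantile normalization; camera adjusted p = 0.0043, adjusted p = 0.640 with an estimated correlation), and this was lost under repeated quantile normalization (0.0740, in a range of 4.49e-07 to 0.0740). The list for the citric acid cycle was shifted lower too, with 10 of 29 lower and 2 higher (camera adjusted p = 0.0130, adjusted p = 0.548 with an estimated correlation), and lost that shift under repeated quantile normalization (0.109), with protein-coding genes only (0.0543) and without dim genes (0.0605), in a range of 0.000339 to 0.109. With the covariate 3 of these were lower, and 6 under repeated quantile normalization.

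Ion channels and receptors separated ganglion from carotid body in both directions. Kcnk3 and Kcnk9 were higher in carotid body than in ganglion (2.83-fold and 95.2-fold), as was Kcnmb1 (4.58-fold). Kcnma1 was under the limit at -0.93 (called without carotid body replicate 1, at -1.10, and with array weights, at -1.03). Trpc5, a receptor-operated cation channel, was at least 30.8-fold higher in carotid body, with 3 of 4 ganglion arrays under the background bound (5.45 ± 0.31), while the acid-sensing channel gene Asic2 was 13.4-fold lower. Of 33 voltage-gated potassium channels 12 were lower, among them Kcnq3 (20.3-fold) and Kcnh5 (12.4-fold), and Kcna1 was higher by 2.05 (camera adjusted p = 0.0159, adjusted p = 0.338 with an estimated correlation). The shift was lost on ranks (0.0528) and with protein-coding genes only (0.0681), in a range of 0.000441 to 0.0681, and Kcnq3 was 13.4-fold lower without carotid body replicate 2. With the covariate Kcna1 (1.59), Chrnb4 (-2.46) and Prkaa1 (-0.65) were no longer called. Of 11 sodium channels 6 were lower, led by Scn9a and Scn2b (14.9-fold and 11.4-fold), and Scn7a was 6.37-fold higher (camera adjusted p = 0.00107, adjusted p = 0.422 with an estimated correlation). The calcium channel subunit Cacna2d3 was lower by 1.99 and Cacna1h higher by 1.42. Among acetylcholine receptors, Chrnb4, Chrm2 and Chrna5 were lower in carotid body by 4.37, 3.81 and 3.76 (Chrnb4 by 5.20 and 3.48 without carotid body replicates 1 and 2). Car2 and Car3 were 18.5-fold and 12.6-fold higher, and Rgs9 7.43-fold lower. Prkaa1 and Prkaa2, the catalytic subunits of AMP-activated kinase, were 2.75-fold and 5.40-fold lower in carotid body, and Hmox2 differed by -0.58, under the limit.

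By cell type, all 24 neuron genes were lower in carotid body than in ganglion (median difference -2.49, camera adjusted p = 1.03e-12, adjusted p = 0.338 with an estimated correlation), among them Ngfr, a neurotrophin receptor, by 4.09 and Ret by 4.33. Without carotid body replicates 1 and 2 these were 5.01 and 3.26 for Ngfr and 5.11 and 3.48 for Ret, and with the covariate 15 of the 24 were lower and Ngfr was no longer called (-2.40). The opposite held for vessels and connective tissue. All 15 endothelial genes were higher in carotid body (median difference 3.29, camera adjusted p = 1.04e-18, adjusted p = 0.0409 with an estimated correlation), such as Eng (35.4-fold) and Cdh5 (18.8-fold). So were 12 of 15 pericyte and smooth muscle genes (camera adjusted p = 1.39e-16, adjusted p = 0.0347 with an estimated correlation) and all 14 fibroblast genes (camera adjusted p = 3.82e-17, adjusted p = 0.00676 with an estimated correlation), led by Dpt and Col1a1 (30.7-fold). Of 12 adipocyte genes 9 were higher (camera adjusted p = 9.61e-09, adjusted p = 0.126 with an estimated correlation), with Fabp4 31.7-fold higher. Glial genes were not shifted as a list (median difference 0.08, camera adjusted p = 0.246), with 1 of 13 called, Fabp7, lower by 1.53 (not called with the covariate, at -1.49), and Erbb3 at 11.34 ± 0.44 against 11.31 ± 0.37 (Cdh19 was also called, higher at 1.28, without carotid body replicate 3 and at 1.27 without ganglion replicate 3). Smaller differences of single glial genes are not excluded. Of 42 cytosolic ribosomal protein genes 9 were higher and 1 lower (camera adjusted p = 5.23e-07, adjusted p = 0.540 with an estimated correlation), but with the covariate none was called and the shift was lost (0.289, in a range of 1.00e-08 to 0.289). The count of higher genes was 15 without carotid body replicate 1, 5 without replicate 3 and 17 under repeated quantile normalization. Of 19 immediate early genes 9 were higher (camera adjusted p = 1.47e-05, adjusted p = 0.338 with an estimated correlation), among them Jun (2.48-fold) and Nr4a2 (2.69-fold).

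The comparison of adrenal medulla with superior cervical ganglion sets the adrenal samples against the sympathetic ganglion. Pnmt averaged 14.13 ± 0.68 in adrenal medulla and 5.18 ± 0.08, under the background bound, in ganglion (at least 411-fold, SE of the log2 difference 0.26, limma adjusted p = 2.11e-09). Slc18a1 was 153-fold higher in adrenal medulla, Chga at least 116-fold higher and Kcnk9 1293-fold higher (16.57 ± 0.12 against 6.23 ± 0.55). Htr3a was 2003-fold higher in ganglion and Tubb3, a neuronal tubulin, 762-fold higher (17.30 ± 0.33 against 7.73 ± 0.25).

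In total 3987 genes were called, 1725 higher and 2262 lower in adrenal medulla (3572 lower with all features tested). Repeated quantile normalization gave 2218 higher and 1896 lower (53.9% higher against 43.3%). Protein-coding genes made up 1337 of those higher and 1733 of those lower, and 200 genes were higher and 511 lower by at least 8-fold. The named genes with the largest differences towards adrenal medulla were again Cyp11b1, Cyp11a1, Star, Hsd3b1 and Cyp21a1, then Adh1 (an alcohol dehydrogenase, higher by 10.45), Kcnk9, Abcb1b, Akr1cl and Pnmt. Towards ganglion they were Htr3a, Htr3b (821-fold), Tubb3, Tspan8 (a tetraspanin, at least 604-fold), Prph (peripherin, 596-fold), Ddah1 (595-fold), Sv2c (a synaptic vesicle protein, at least 561-fold), Tubb2b (374-fold), Ret (a neurotrophic factor receptor, 362-fold) and Sncg (gamma-synuclein, 307-fold).

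Among catecholamine genes Th was not called (19.57 ± 0.09 in adrenal medulla, 19.22 ± 0.10 in ganglion), but its adrenal medulla level lay near the top of the range, so the difference of 0.35 is a lower bound. Dbh was at the top of the range in both tissues, which leaves its difference unmeasured. Slc18a2 was 8.19-fold lower in adrenal medulla, Slc6a2 123-fold lower and Maoa, another monoamine-degrading enzyme, 33.1-fold lower. In all 2 of 15 genes were higher and 6 lower without a shift of the list (camera adjusted p = 0.511). Of 14 granule genes 4 were higher and 1 lower (camera adjusted p = 0.0120, adjusted p = 0.563 with an estimated correlation), with Scg2 39.8-fold higher. The shift was lost on ranks (0.0562) and without dim genes (0.0985), in a range of 0.000723 to 0.0985. Npy and Gal were 7.19-fold and 5.20-fold higher. In the hypoxia-inducible factor pathway, 6 of 18 genes were higher, including Epas1 (6.63-fold), Adm (44.7-fold) and Arnt2 (15.4-fold), and 2 lower (Ndrg1 and Egln3, by 2.51 and 2.15), and the list was not shifted (camera adjusted p = 0.102) except with all features tested (0.0231, in a range of 0.0231 to 0.286, and 0.374 with an estimated correlation). Hif1a was called at 1.07, but not without ganglion replicate 2 (0.98). Ndufa4l2 was at least 215-fold higher in adrenal medulla, Pcx and Cox4i2 were higher by 2.68 and 1.08, and Cox8b was at least 4.81-fold higher, as its ganglion level lay under the background bound. Kcnk3, Kcnk2 and Kcnma1 were 93.7-fold, 11.6-fold and 3.52-fold higher. In contrast 14 of 33 voltage-gated potassium channels and 8 of 11 sodium channels were lower and none of either was higher (camera adjusted p = 0.000976 and 7.97e-07, adjusted p = 0.195 and 0.281 with an estimated correlation).

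Neuron genes were lower in adrenal medulla for 23 of 24 (median difference -3.15, camera adjusted p = 1.12e-14, adjusted p = 0.332 with an estimated correlation). In turn 12 of 13 adrenal cortex genes were higher (camera adjusted p = 2.00e-18, adjusted p = 0.0347 with an estimated correlation), with Cyp11b1 at least 18326-fold higher. Endothelial genes were higher for 12 of 15 (camera adjusted p = 1.49e-13, adjusted p = 0.0962 with an estimated correlation), among them Plvap (87.2-fold) and Emcn (84.4-fold). Glial genes were lower for 8 of 13 (camera adjusted p = 0.000148, adjusted p = 0.126 with an estimated correlation), with Fabp7 33.2-fold lower. Glycolysis genes were lower for 10 of 18 (camera adjusted p = 7.69e-05, adjusted p = 0.422 with an estimated correlation), and genes of complexes II to V for 11 of 38 (camera adjusted p = 0.000968, adjusted p = 0.563 with an estimated correlation; 8 without ganglion replicate 2 and 7 under repeated quantile normalization). The smaller shift of complex I (camera adjusted p = 0.0422, adjusted p = 0.767 with an estimated correlation) was lost with protein-coding genes only (0.0597) and without adrenal medulla replicate 2 (0.0528), 3 (0.0618) or 4 (0.0721), carotid body replicate 2 (0.0502), or ganglion replicate 2 (0.0972) or 3 (0.0936), in a range of 0.0119 to 0.0972. Immediate early genes were higher for 9 of 19 (camera adjusted p = 0.000148, adjusted p = 0.364 with an estimated correlation), with Fosl2, a subunit of the AP-1 factor, 51.7-fold higher and Jun 9.92-fold higher.

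Across the 3 comparisons, 50 of the 114 list tests were shifted (15, 17 and 18 in the order above), and 7 held with an estimated correlation (3, 3 and 1). Counts of called members were the same adjusted over the list alone in 120 of the 123 combinations of list and comparison. The exceptions were the olfactory receptors, where the 2 called higher in carotid body against each other tissue became 1 and 1 over the list alone, and the background families, where the 2 called lower in adrenal medulla than in ganglion became 1. Those 2 were 4 without ganglion replicate 2 and 1 without adrenal medulla replicate 2 or ganglion replicate 1, without dim genes, under median centring or under repeated quantile normalization. Median, mean and test had one sign in every shifted list and differed in 20 of the 64 tests that were not shifted. Some shifts came from lists with few called members. Monoamine receptors were shifted higher in carotid body than in adrenal medulla (3 of 21 higher, camera adjusted p = 0.0018, adjusted p = 0.338 with an estimated correlation) and lower in adrenal medulla than in ganglion (3 lower, camera adjusted p = 0.0361, adjusted p = 0.493 with an estimated correlation). The latter was lost under repeated quantile normalization (0.0597), on ranks (0.0507), without dim genes (0.0796) and without ganglion replicate 4 (0.0501), in a range of 0.0196 to 0.0796. Also shifted higher in carotid body than in adrenal medulla were the sensory neuron markers (3 of 13 higher, camera adjusted p = 0.00679, adjusted p = 0.323 with an estimated correlation), the purinergic receptors (2 of 14, camera adjusted p = 0.0228, adjusted p = 0.374 with an estimated correlation). The camera test called the skeletal muscle markers shifted too (camera adjusted p = 0.0209, adjusted p = 0.780 with an estimated correlation), though 0 of 19 were called (4 without carotid body replicate 1, and 1 without replicate 3, without dim genes or with protein-coding genes only). The purinergic shift was lost with the covariate (0.0929, in a range of 0.0144 to 0.0929). The muscle shift was lost with the covariate (0.742), with array weights (0.0514), without dim genes (0.0796) and without carotid body replicate 2 (0.102), in a range of 0.00137 to 0.742. Macrophage markers were shifted lower in ganglion than in carotid body (2 of 14 called, 7 without carotid body replicate 1, 4 without ganglion replicate 2 or 3, with array weights or under repeated quantile normalization, camera adjusted p = 0.00858, adjusted p = 0.640 with an estimated correlation) and than in adrenal medulla (5 higher and 1 lower in adrenal medulla, none lower without adrenal medulla replicate 2 or ganglion replicate 2 or 3, with the covariate, under median centring or under repeated quantile normalization, camera adjusted p = 0.0114, adjusted p = 0.647 with an estimated correlation). The former was lost with the covariate (0.823, with 1 gene lower in carotid body and none higher, in a range of 0.00225 to 0.823) and the latter without dim genes (0.0968, in a range of 0.000684 to 0.0968). For adrenal medulla against ganglion, pericyte genes (6 of 15, camera adjusted p = 2.70e-05, adjusted p = 0.279 with an estimated correlation) and ribosomal protein genes (6 of 42, 11 under repeated quantile normalization, camera adjusted p = 1.74e-07, adjusted p = 0.510 with an estimated correlation) were shifted higher. Fibroblast genes were shifted lower (6 of 14 lower, 1 higher, camera adjusted p = 0.0195, adjusted p = 0.338 with an estimated correlation), though not on ranks (0.0507, in a range of 0.00498 to 0.0507). Olfactory receptors and the background families were shifted lower there too (camera adjusted p = 0.0220 and 0.0134, adjusted p = 0.803 and 0.763 with an estimated correlation), and neither was without dim genes (0.602 and 0.426). The olfactory shift was also lost with array weights (0.0588) and without ganglion replicate 1 (0.0557) or 4 (0.0623), in a range of 0.00874 to 0.602, and the range for the background families was 0.00369 to 0.426.

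Among 1083 olfactory receptors, 3 were called between carotid body and adrenal medulla (8 with the covariate and 5 without carotid body replicate 1), 2 between carotid body and ganglion (4 without carotid body replicate 1 or ganglion replicate 1 or with array weights) and 3 between adrenal medulla and ganglion. Olfr78 is not among the 1083, since its cluster, like that of Higd1c, pairs with several symbols and was left unnamed. In the lists of lymphocyte, proliferation, blood cell and Y-linked genes limma called none (1 proliferation gene was called against ganglion in carotid body with the covariate, and in adrenal medulla with array weights, under median centring and without adrenal medulla replicate 1 or ganglion replicate 1). At an unadjusted p under 0.05 there were 2, 1 and 3 of 14 lymphocyte genes in the 3 comparisons, 0, 2 and 4 of 14 proliferation genes, 0 of 2 blood cell genes and 2, 0 and 2 of 3 Y-linked genes. Xist was not called (1, 0 and 0 at that level). In each comparison 2 of 10 thyroid and parathyroid genes were called (1 with the covariate and 3 without carotid body replicate 1 in both carotid body comparisons). Of the sensory neuron list of 13, Ntrk3, a neurotrophin receptor, was higher in carotid body (11.35 ± 0.07) than in ganglion (8.11 ± 0.12) and adrenal medulla (6.53 ± 0.07), and Avil (advillin) was highest in ganglion.

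Genes higher in one tissue than in both others numbered 728 for carotid body, 738 for adrenal medulla and 1529 for ganglion. In carotid body the named genes with the largest smaller difference were Acta2, Cpa3, Cytl1, Slc9a2 (a sodium-proton exchanger, 11.01 ± 0.32 against 4.58 ± 0.13 in adrenal medulla and 4.85 ± 0.25 in ganglion), Myh11 (a smooth muscle myosin), Mcpt4 (a mast cell protease, 11.22 ± 0.78), Rgs5, Cyp2e1, Dpt and Lef1 (a transcription factor of the Wnt pathway, 10.57 ± 0.46). In adrenal medulla they were the steroidogenic genes with Abcb1b, Akr1cl, Pnmt, Slc18a1 and Scarb1, a lipoprotein receptor (14.67 ± 0.04). In ganglion they were led by Cxcr4, Napb, Htr3a, Nrip3, Htr3b, Sult4a1 and Nefl. Carotid body and adrenal medulla shared 686 genes higher and 1529 lower than in ganglion, the former including Ndufa4l2, Epas1, Adm, Kcnk9, Kcnk3, Trpc5 and Gdf10. These examples were taken from genes already named, as the naming rule does not cover the shared genes. The shared higher genes also held 12 of 15 endothelial markers. Which cells held the shared transcripts was not tested. The contrasts behind the counts of genes higher in 1 tissue and of shared genes have arrays in common. Unchanged simulated groups gave 0 genes in each count. No gene of these groups was changed, so the 0 does not show what shared arrays add among changed genes. Independent lists of these sizes, drawn from all tested genes with dim ones included, would overlap in 103 genes for carotid body, 85.4 for adrenal medulla, 187 for ganglion (also the shared lower genes) and 96.8 for the shared higher genes. With the shared tissue's arrays split between the contrasts, the counts were 685 to 740 for adrenal medulla, 1389 to 1534 for ganglion and 580 to 644 for the shared higher genes. The carotid body has too few arrays to split, and its 728 became 430 with the covariate, 448 with protein-coding genes only, 1344 with all features tested and 587 to 1082 without 1 array.

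The arrays of one tissue were not equally alike. Genes of neuron structure and synapse had a median of 11.96 on carotid body replicate 1, 10.08 on replicate 2 and 11.05 on replicate 3, against 7.60 to 8.18 on the adrenal medulla arrays and 13.65 to 14.22 on the ganglion arrays. The SD among carotid body arrays was 1.83 for Slc6a2, 1.78 for Nefl, 1.69 for Htr3a and 1.47 for Dbh, against 0.48 for Epas1 and 0.20 for Rgs5. Without carotid body replicate 1 the number of genes called against adrenal medulla went from 3320 to 3740 and without replicate 2 to 3128, and against ganglion from 4187 to 4778 and 3738.

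**Figure D3:**
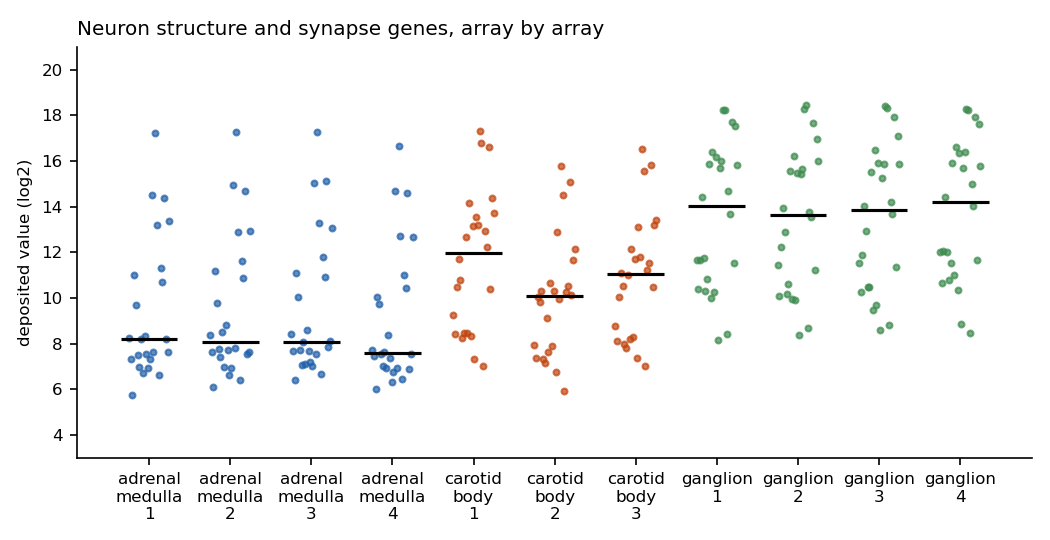
Deposited log2 value (vertical axis) of the 24 genes of neuron structure and synapse on each of the 11 arrays (horizontal axis), one point per gene and a black line at the median. The medians of the carotid body arrays are 11.96, 10.08 and 11.05, above all adrenal medulla arrays and below all ganglion arrays.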

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

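The tests of ganglion RNA, of an array quality effect alike on bright genes and of a lower share of the main cell type were chosen after the result was seen, while the splits of the arrays and the tests of cortex and adipose tissue were set beforehand. For carotid body against adrenal medulla, 1 of the 35 splits of the 7 arrays, the real one, gave as many genes (3269 in a fit of both tissues alone, 0 at most in the other splits). For carotid body against ganglion it was again 1 of 35 (4091 against at most 0), and for adrenal medulla against ganglion 1 of 35 (4049 against at most 0). No share below 1 of 35 could be reached, and splits that mix distinct tissues widen the spread within each group. These counts therefore show only that the tissues differ.

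Genes of the ganglion were spread among the carotid body arrays: of 137 protein-coding genes with a ganglion mean of at least 12 and called at least 8-fold higher there than in adrenal medulla, replicate 1 was the highest carotid body array for 126 (92.0%, against 24.4% of all genes) and replicate 2 the lowest for 125, with a median excess of 1.05 on replicate 1. An array quality effect alike on all bright genes is argued against, as the same excess was -0.0025 in 59 bright carotid body genes. The gap between positive and negative control features (4.74, 4.20 and 4.42 on replicates 1 to 3) nevertheless has the order of the ganglion genes (-2.40, -3.80 and -3.03 against ganglion) and is narrower than on any adrenal medulla array (5.13 to 5.47) or ganglion array (4.92 to 5.53), and 32, 97 and 84 features lay at the arrays' maxima, so a quality effect that differs among transcripts stays open. Ganglion RNA in unequal shares stays open too: with a share of 8.58% fitted on 69 of the genes, 10.3% of the other 68 had an excess more than 1 log2 unit under it, but the excess varied no less among genes as a share of the ganglion level (median absolute deviation 0.80) than as a fold (0.69), so it cannot be told apart from a rise by a common factor, and neurons or nerve endings of the carotid body itself were not tested. This test replaced, after the results were seen, one that could hardly fail (replicates 2 and 3 alone would meet its bound for 73.7% of the genes), and the genes were limited to protein-coding ones after all 270 had been tried (replicate 1 highest for 136, excess in 73 bright genes -0.13).

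Genes of the adrenal cortex lay near the top of the range on the adrenal medulla arrays, with Cyp11b1 at 19.61 and Star at 18.42. Cortex tissue in the adrenal medulla samples may account for them, and 12 of 13 genes of the fixed list were higher than in carotid body and 12 of 13 higher than in ganglion. Of 8 further cortex genes 3 were higher in adrenal medulla than in both other tissues, which is under the bound set beforehand but by less than the binomial standard error, a margin put in after the counts were seen. The further genes are a weak test, since some of them are dim everywhere. Akr1c18 and Pik3c2g, named outside the rule, averaged 4.78 and 4.61 in adrenal medulla and lay under the background bound in every tissue. This count therefore leaves the question open, and expression by medullary cells was not tested.

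Genes of adipocytes were higher on the carotid body arrays, with Fabp4 at 14.07 and Retn at 10.66. Adipose tissue in the carotid body pools may account for this, and 4 of 11 further adipocyte genes were higher than in both other tissues, again under the bound set beforehand by less than the margin put in afterwards, so it stays open. Acvr1c, Pnpla3, Slc2a4 and Cd36, named outside the rule, were also higher against both at a limma adjusted p under 0.05. Each was under the 2-fold limit against at least 1 of them, so the count depends on that limit. Gpd1, Agpat2 and Scd1, also outside the rule, were not higher than in both. The medians of the adipocyte, fibroblast, endothelial and macrophage lists against adrenal medulla (2.81, 4.66, -0.18 and -0.05) span 4.83. A lower share of the main cell type alone would move them alike only if the other cells were mixed alike in both organs. Only that narrow case is argued against. A difference in the make-up of the tissues themselves was not tested.

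In 18 of 294 groups of 4 arrays, 1 array stood apart from the other 3, where chance gives about 1 in 20. On adrenal medulla arrays these were Dbh on replicate 4 (19.84), Maob on replicate 4 (12.30), Kcnk3 on replicate 2 (14.67), Tubb3 on replicate 3 (8.11), Cdh5 on replicate 4 (12.19), Cyp21a1 on replicate 3 (18.27), Abcb1b on replicate 3 (17.49), Cyp2e1 on replicate 2 (5.05) and Itga8 on replicate 1 (9.57). On ganglion arrays they were Pck1 on replicate 1 (6.90), Kcnmb1 on replicate 2 (5.77), Cacna1d on replicate 2 (6.77), Car3 on replicate 1 (10.97), Dpt on replicate 2 (8.48), Retn on replicate 2 (6.70), Cdo1 on replicate 2 (10.69), Ccl11 on replicate 2 (11.20) and Xist on replicate 4 (5.28). For Dbh, Itga8, Retn and Cdo1 the other 3 arrays had identical values, so a gap of any size passes. For Dbh that gap was 19.8382 against 19.845, near the arrays' maximum. Of 35349 transcript clusters without a single gene symbol, 14113 had a mean above the background bound in at least 1 tissue. Of these 14113, 1751 were called between carotid body and adrenal medulla, 1953 between carotid body and ganglion and 1849 between adrenal medulla and ganglion.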

How the results depend on the processing

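The covariate for the control features, protein-coding genes only and the fits with identical profiles counted once were chosen after the result was seen. For 145 named genes, 352 of 435 differences were called, and of 10431 values under the 24 alternatives that give values of genes 2 reversed. Both came with the covariate: carotid body minus adrenal medulla went from -1.84 to 0.28 for Chrnb4 and from 1.10 to -0.0758 for Ndufa4 (adjusted p 0.00111 to 0.865 and 0.00145 to 0.916 over the alternatives). With the covariate the lower levels in carotid body were no longer called against ganglion for Th (-0.83) and Slc6a2 (-2.06), nor for Dbh against either tissue, where its levels near the maximum leave the size of the difference unmeasured. In all 18 of the 352 calls were lost with it and 109 differences moved by over 1.5-fold. The cause was not tested.

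With all features tested, carotid body and adrenal medulla differed in 5157 (3236 higher), 2885 were higher in carotid body than in ganglion, 3572 lower in adrenal medulla than in ganglion and 1344 higher in carotid body than in both. Without a fold limit, which can only add genes, the counts were 8833 for carotid body against adrenal medulla (4139 higher, 4694 lower), 10271 for carotid body against ganglion (4286 and 5985) and 10364 for adrenal medulla against ganglion (4700 and 5664). Those higher in 1 tissue than in both others were then 1891, 2454 and 3646 for carotid body, adrenal medulla and ganglion, and the shared ones 2211 higher and 3646 lower. With an estimated correlation 3, 3 and 1 lists were shifted. The control gap was narrower on all carotid body arrays than on the others, so this covariate moves with tissue. It gave 2483 genes for carotid body against adrenal medulla, of which 1888 are among the 3320, 2791 for carotid body against ganglion (1011 higher), of which 2424 are among the 4187, and 430 highest in carotid body. Protein-coding genes only gave 1002 higher in carotid body than in adrenal medulla, 1015 than in ganglion and 448 than in both.

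Without each array in turn the counts ranged from 3128 to 3740 for carotid body against adrenal medulla, from 3738 to 4778 against ganglion and from 587 to 1082 for genes highest in carotid body, each with the ends without carotid body replicates 2 and 1. For adrenal medulla against ganglion they ranged from 3913 to 4095, without adrenal medulla replicates 1 and 4. Single arrays changed the calls of carotid body minus adrenal medulla for Chrnb4 (-0.95 without carotid body replicate 2; the call was lost without any array other than carotid body replicate 1), Abcc9 (1.09, and 0.87 without carotid body replicate 1) and Egr1 (-1.15, and -0.91 without adrenal medulla replicate 1; the call was also lost without adrenal medulla replicate 4, carotid body replicate 2 or carotid body replicate 3, with adjusted p from 0.00227 to 0.516 over the alternatives). Cox5a was called at -1.24 against ganglion but not without carotid body replicate 1 (-0.99).

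No pairing by replicate number was seen. Across genes, r between deviations from the tissue means was -0.17 to 0.25 in 10 pairs of same-numbered arrays and -0.34 to 0.34 between other numbers. These correlations cannot show whether same-numbered pools shared mice or a session, which the labels do not say. With the number as a block the counts were 3302, 4115 and 3986.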

Other observations

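The lists of further mast cell genes and the look at ribosomal RNA genes were chosen after the values were seen. Mast cell proteases were among the genes highest in carotid body: beside Cpa3 and Mcpt4, Tpsb2 averaged 10.04 against 4.58 in adrenal medulla and 5.10 in ganglion and Cma1 averaged 7.98, with both other tissues under their background bounds. Of 9 further mast cell genes these 2 were higher in carotid body than in both other tissues, while Kit was highest in ganglion (8.71, against 7.23 in carotid body and 6.18 in adrenal medulla).

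Of 34 ribosomal RNA genes, 32 were higher in carotid body than in adrenal medulla and 32 lower in adrenal medulla than in ganglion, and most of them share their values with one another.

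Xist averaged 4.96 in adrenal medulla, 5.35 in carotid body and 5.11 in ganglion, each under the background bound, although the labels give mice of both sexes. The Y-linked genes Eif2s3y (9.40, 9.09 and 9.13) and Uty (9.52, 8.93 and 9.18), named outside the rule like Tpsb2, Cma1 and Kit, were expressed in all 3 tissues. Whether the array's Xist features respond was not tested.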
